A study of Mus musculus with 96 samples.

How the data were processed

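The data were gene counts from 96 liver libraries of 12 mice, 6 given phenobarbital and 6 controls, with each liver kept in 8 ways. Libraries were strand-specific and depleted of ribosomal RNA, per the labels. The submitters' processing notes list CASAVA, STAR 2.5 and edgeR and the builds GRCm38 and mm10 without giving their roles. The tool that counted reads, its gene annotation and its strand setting are not given in the sources used here, so antisense and overlapping genes, and genes with near-identical copies, carry an uncertainty in counting. The kits used to isolate RNA from the ethanol, 18-hour formalin, 3-month formalin and TAE portions are not given in the part of the protocol used here, so kit and preservation are not separated in comparisons with other states.

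Deposited raw counts per Ensembl gene, in whole numbers and not normalized, were the basis of every test. A second deposited table held log2 values, which the values show to be log2 of CPM by the authors, made after adding 0.05 to each count and with one scaling factor per library. That table served only one alternative. The count table had 47465 lines, 92 of them spike-in controls, which were kept out of library totals and tests and held 110 counts in all. Of the 47373 genes 46954 matched GENCODE M21 on GRCm38, which gave symbols, coordinates, lengths and GC content, and the other 419 held at most 0.0502% of the counts of any library. Coordinates are 1-based GRCm38 positions of whole genes from that annotation, which may differ from the one used for counting.

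Groups came from the sample titles and preservation labels. Library totals ran from 1264563 to 18442730 counts. A gene with 0 counts in a group was given a floor of 3 counts over that group, which covers counting error only, since reads without molecular identifiers are not independent molecules. No 2 libraries held identical counts.

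Differential expression was tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test, with TMM scaling, the default low-count filter by group and Benjamini-Hochberg adjustment at 0.05. In that filter a gene needs about 10 counts at the median library size in as many libraries as the smaller group holds. Standard errors are the log2 fold change divided by the square root of F. Phenobarbital was compared with control within each state, 6 against 6. The 14 comparisons between states used 12 libraries each side with treatment as a covariate, and 7 interaction fits over 24 libraries tested whether the phenobarbital effect in a preserved state differed from that in frozen liver. Levels are CPM with TMM scaling, averaged over the group.

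Gene lists, 38 in number with 935 entries, were fixed before the data were examined, as were the groups, the tests, the first alternatives below and the rule for genes named. Of the entries 922 were found as written and 6 through an older symbol. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and again at an estimated correlation, adjusted over the lists of a comparison, and members were also adjusted over the list alone. Genes were named by rule: 10 fixed genes, the 8 largest rises and falls past the threshold with a mean of at least 5 CPM and group ranges that did not overlap in frozen phenobarbital and state comparisons, up to 4 called and 2 uncalled members of a described list, and the 5 smallest p of an interaction if past the threshold. Predicted genes without a symbol of their own were passed over.

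Library totals, genes detected after thinning to 1264563 counts, the share of the 10 most abundant genes and the share of mitochondrially encoded genes were compared with frozen per animal by a two-sided permutation test over all sign changes, adjusted over the family. Differences in mitochondrial share between phenobarbital and control used exact two-sided permutation tests. The animals pair the libraries across states, since titles carry the animal. Over 10197 genes, the correlation of deviations from group means was above 0.1 in 336 of 336 same-animal pairs (median 0.673, against -0.127 for other animals). The animal entered as a block as an alternative.

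Alternatives were DESeq2 1.42.0, limma voom with quality weights, no filter, 1 gene set for all comparisons, RLE scaling, library totals alone, thinning to the shallowest library, the block, and each animal left out in turn in the phenobarbital comparisons. Alternatives chosen after seeing the data left out the shallowest library, the library richest in small RNAs or the heat-only library with the highest mitochondrial share, thinned to the second lowest total, removed a smooth trend on length or GC content from blocked fold changes, or used limma on the deposited log2 values. On simulated counts with 200 changed genes built from the real libraries, the frozen phenobarbital test recovered 59.7% of 1.5-fold, 80.6% of 2-fold and 97% of 4-fold changes. The interaction test of 3-month formalin recovered 44.8% of 2-fold differences, or 68.7% with the animal as a block. A result on 1 withheld item is not reported here.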

Results

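Liver RNA was profiled from 12 male B6C3F1 mice, a hybrid strain widely used in toxicology. Phenobarbital, a barbiturate that activates the nuclear receptor CAR and induces hepatic drug metabolism, was given in the drinking water at 600 ppm for 7 days to 6 mice. The other 6 were controls. Portions of each liver were kept in 8 ways, so that every animal contributed 1 library to each state and each of the 16 groups held 6 libraries. The reference portions stayed frozen. Per the labels, all fixed portions were made from frozen liver of mixed lobes. Embedding in paraffin followed 3 months in ethanol, 18 hours in formalin and then ethanol to 3 months, or 3 months in formalin. Material from the 3-month formalin state was also worked up in 4 further ways meant to remove formalin adducts from RNA. Isolated RNA was heated for 30 minutes at 70 °C in TAE, a Tris-acetate-EDTA buffer. Alternatively, the portions were incubated for 18 hours at 55 °C with an organocatalyst and isolated with an AllPrep or a PureLink kit. Incubation for the same time without catalyst, followed by AllPrep, is called heat only here. Strand-specific total RNA libraries depleted of ribosomal RNA were counted per gene. The 96 libraries held 1264563 to 18442730 counts on genes, with a median of 11913138. Mean totals were 15643920 ± 1177567 (SD, n = 12) in frozen and 8112837 ± 2468143 (n = 12) in 3-month formalin portions.

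The first comparison asked whether preservation changed the makeup of the libraries. Mitochondrially encoded genes took 2.57% ± 0.405 (SD, n = 12) of the counts in frozen liver and 9.92% ± 2.4 after 3 months in formalin. Of the 13 mitochondrially encoded protein genes 6 held 220 counts together over the 96 libraries, so the share holds almost nothing of them and the lists below rest on the other 7. The paired difference in share was 7.36 percentage points, positive in 12 of 12 animals. The share was also above frozen in 12 of 12 animals in the TAE portions (6.4%), the heat-only portions (8.29%), the AllPrep catalyst portions (4.84%) and the PureLink catalyst portions (4.56%). Each had an exact paired permutation p of 0.000488, the smallest that 12 pairs can give (adjusted p = 0.000804). In the ethanol and 18-hour formalin portions it was 2.74% (exact permutation, adjusted p = 0.199, higher in 8 of 12) and 2.59% (adjusted p = 0.806, higher in 6 of 12). The 10 most abundant genes together took 16% of frozen counts and 18.2% of 3-month formalin counts (adjusted p = 0.00144, higher in 11 of 12). Without the mitochondrially encoded genes that difference turned to -2.06 percentage points. Thinned to equal totals, PureLink catalyst libraries held 873 more detected genes than frozen ones (adjusted p = 0.000804, 12 of 12 animals). After 3 months in formalin the difference was -150 genes (adjusted p = 0.0957). Without mitochondrially encoded genes it turned to 31.1 (8 of 12 animals higher, adjusted p = 0.721).

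**Figure D1:**
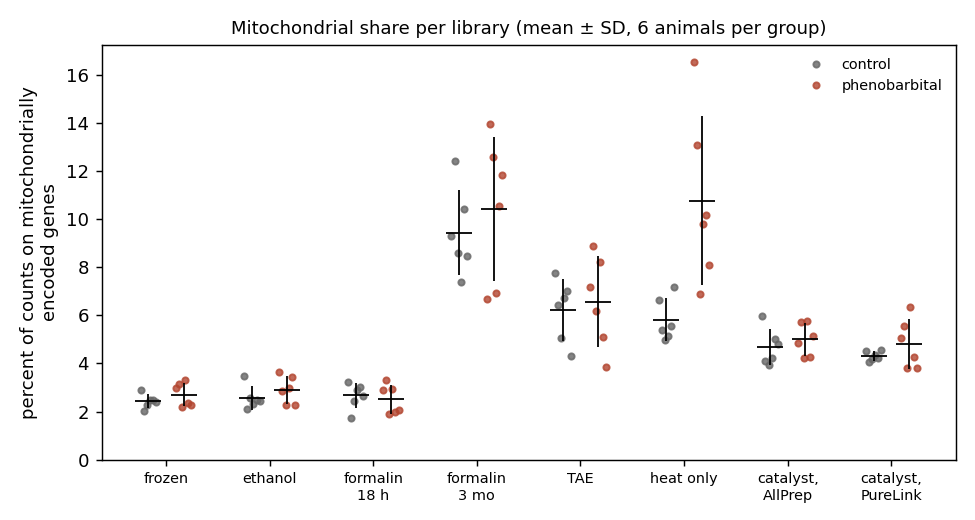
Percent of each library's counts on mitochondrially encoded genes (vertical axis) in the 8 preservation states (horizontal axis), with 1 point per animal, grey for control and red for phenobarbital, and bars for mean ± SD of 6 animals. The frozen, ethanol and 18-hour formalin groups lie lowest, and the heat-only phenobarbital group averages 10.8% against 5.82% in its controls.

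The effect of phenobarbital was measured first in frozen liver, 6 treated against 6 control animals. Cyp2b10, the P450 that serves as the standard marker of CAR activation (ENSMUSG00000030483, chromosome 7, 25897620 to 25926624), rose by a log2 fold change of 13.42 ± 0.29 (SE), from 0.198 to 2279 CPM, with an adjusted p of 1.49e-12. Cyp2c55 (ENSMUSG00000025002, chromosome 19, 39007019 to 39042693) rose by 8.74 ± 0.26 and the pseudogene Cyp2c53-ps by 7.99 ± 0.25. Cyp2c66, another member of that family, had 0 counts in the controls and 16.7 CPM with phenobarbital, at least 453-fold higher against a floor of 3 counts over the control group. Cyp3a11, the main CYP3A enzyme of mouse liver (ENSMUSG00000056035, chromosome 5, 145854426 to 145879964), rose by 5.90 ± 0.47 to 8713 CPM and Cyp2c29 by 4.41 ± 0.35 to 6892 CPM. The glutathione S-transferase gene Gstm3 rose by 6.07 ± 0.34, the epithelial keratin gene Krt4 by 7.80 ± 0.43 and the aldo-keto reductase gene Akr1b7 by 5.74 ± 0.79. Por, the reductase that passes electrons to microsomal P450s, rose by 2.46 ± 0.24. In total 1313 of 13929 genes tested changed, 821 higher and 492 lower, and 872 changed without the treated animal 80B.

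Genes of drug metabolism rose as a group. Of 19 measured CYP2B, CYP2C and CYP3A genes 13 rose and 0 fell (median 3.70, 14 adjusted over the list alone, camera adjusted p = 2.85e-21, adjusted p = 0.034 with an estimated correlation). The abundant Cyp2c70 (0.34 ± 0.14, adjusted p = 0.156) and Cyp2c67 (-0.46 ± 0.18, adjusted p = 0.131) did not pass. The median of this list does not depend on Cyp2c66, which lies above it also at its bound. Among 23 other P450 and redox partner genes 11 rose and 0 fell (median 0.39, 14 adjusted over the list alone, camera adjusted p = 1.18e-08, adjusted p = 0.211 with an estimated correlation). Among them were Cyp2a5, a coumarin hydroxylase, at 3.40 ± 0.29, the microsomal epoxide hydrolase Ephx1 at 1.84 ± 0.16 and Cyp1a2 at 1.60 ± 0.14. For conjugation enzymes the counts were 27 higher and 0 lower of 48 (median 0.59, 32 adjusted over the list alone, camera adjusted p = 2.15e-22, adjusted p = 0.0731 with an estimated correlation). The higher ones included Gsta1 (6.13 ± 0.93), the oestrogen sulfotransferase Sult1e1 (4.39 ± 0.87) and Gstt3 (3.56 ± 0.20). Carboxylesterases, aldehyde dehydrogenases and aldo-keto reductases gave 15 higher and 0 lower of 27 (median 0.40, 15 adjusted over the list alone, camera adjusted p = 4.48e-12, adjusted p = 0.186 with an estimated correlation). Ces2a rose by 3.40 ± 0.19 and the retinal dehydrogenase Aldh1a1 by 1.88 ± 0.18. The drug exporter gene Abcc3 rose by 3.24 ± 0.35. NRF2 targets, the genes of the oxidative stress response, gave 7 higher and 0 lower of 14 (median 0.31, 7 adjusted over the list alone, camera adjusted p = 1.3e-05, adjusted p = 0.211 with an estimated correlation). The quinone reductase Nqo1 rose by 1.52 ± 0.29.

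Proliferation genes were higher as well. The marker Mki67 (ENSMUSG00000031004, chromosome 7, 135689784 to 135716361) rose by 2.36 ± 0.46 (adjusted p = 0.00563). Of 28 measured cell cycle genes 23 rose and 0 fell (median 2.00, 26 adjusted over the list alone, camera adjusted p = 9.04e-15, adjusted p = 0.354 with an estimated correlation). Cdc20, an activator of the anaphase-promoting complex, rose by 3.76 ± 0.58 and the mitotic cyclin gene Ccnb1 by 3.19 ± 0.60. The replication genes Mcm7 (0.38 ± 0.14, adjusted p = 0.1) and Pcna (0.55 ± 0.17, adjusted p = 0.0617) did not pass. Pcna passed with DESeq2 (adjusted p = 0.0214), with no filter (0.0496), with scaling by library totals (0.0445) and without the treated animal 75C (0.00606). Among 18 genes linked to CAR-dependent growth and stress 6 rose and 2 fell (median 0.21, 7 adjusted over the list alone, camera adjusted p = 0.00771, adjusted p = 0.211 with an estimated correlation). They included the growth arrest gene Gadd45b (3.92 ± 0.55), the secreted Wnt target Ccn4 (2.92 ± 0.12) and the imprinted noncoding RNA Meg3 (1.64 ± 0.24). Rian, transcribed from the same imprinted region as Meg3, rose by 2.36 ± 0.22. Cytosolic ribosomal protein genes gave 41 higher and 0 lower of 77 (median 0.23, 71 adjusted over the list alone, camera adjusted p = 2.24e-28, adjusted p = 0.284 with an estimated correlation). The rise of Rpl39 was 0.50 ± 0.13. That gene's call (adjusted p = 0.0265) was lost at equal thinned depth (0.442) and when single animals were left out (0.0552 without control 8A, 0.0502 without control 21C, 0.0595 without treated 20B and 0.061 without treated 80B).

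The falls were smaller. Ntrk2, which encodes a neurotrophin receptor (ENSMUSG00000055254, chromosome 13, 58806569 to 59133970), fell by 2.94 (log2 fold change -2.94 ± 0.34, adjusted p = 0.000119). The antisense transcript Ctcflos changed by -1.81 ± 0.20, and strand use in counting is not stated, so reads of an overlapping gene cannot be excluded. Pck1, the gluconeogenic phosphoenolpyruvate carboxykinase, fell from 2267 to 880 CPM (log2 fold change -1.38 ± 0.21). The mitochondrial glutamate carrier Slc25a22 (-1.16 ± 0.14), Cyp2d40 (-1.06 ± 0.12) and the interleukin 6 receptor gene Il6ra (-0.88 ± 0.12) also fell. Of 25 PPARα targets and fatty acid oxidation genes 6 fell and 1 rose (median -0.17, 8 adjusted over the list alone, camera adjusted p = 0.0117, adjusted p = 0.813 with an estimated correlation). Those lower included Fgf21 (-2.07 ± 0.50), a hepatokine of fasting, and Ppara itself (-0.82 ± 0.15). Alas1, the rate-limiting enzyme of heme synthesis, was at 0.95 ± 0.57, adjusted p = 0.33, and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at -0.37 ± 0.35, adjusted p = 0.559, and neither passed. P450, transferase and carboxylesterase genes have close paralogs and pseudogenes, and counting could have split or shared their reads.

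**Figure D2:**
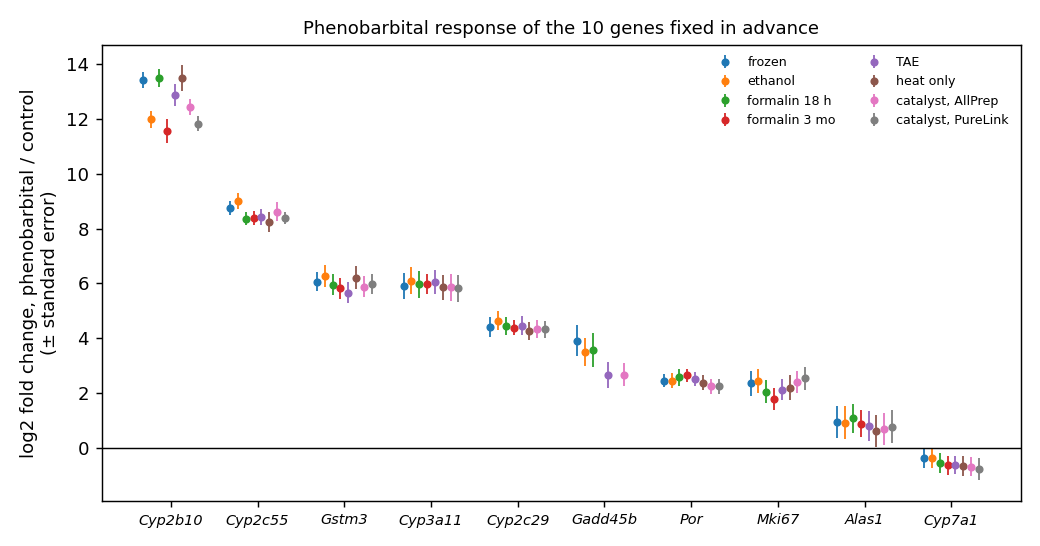
Log2 fold change of phenobarbital over control (vertical axis, point ± standard error, 6 against 6 animals) for the 10 genes named in advance (horizontal axis), with 1 colour per preservation state. Cyp2b10 lies between 11.56 and 13.48 in the 8 states and Por between 2.25 and 2.65, and Gadd45b has no point in the 3 states where the low-count filter removed it.

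The same contrast was then made within each of the 7 other states, 6 against 6 animals each time, to ask whether the phenobarbital response was measurable in preserved tissue. Cyp2b10, Cyp2c55, Cyp2c29, Cyp3a11, Por, Gstm3 and Mki67 rose in all 8 states. Their log2 fold changes spanned 8.25 to 9.01 for Cyp2c55, 4.27 to 4.64 for Cyp2c29, 5.82 to 6.09 for Cyp3a11, 5.66 to 6.26 for Gstm3 and 1.78 to 2.55 for Mki67. Gadd45b rose in the 5 states where it was tested, by 2.66 to 3.92. It was removed by the low-count filter in 3-month formalin, heat-only and PureLink catalyst portions, where at least 1 treated library had fewer than 10 counts. Alas1 and Cyp7a1 passed in 0 of the 8 states, with log2 fold changes of 0.63 to 1.09 and -0.77 to -0.37.

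In ethanol-fixed liver Cyp2b10 rose by 11.98 ± 0.30 (adjusted p = 1.57e-11), Cyp2g1, a P450 best known from olfactory tissue, by 2.68 ± 0.43 and the mitotic kinase gene Plk1 by 3.11 ± 0.50. CYP2B, CYP2C and CYP3A genes gave 12 higher and 0 lower of 19 (median 3.92, 13 adjusted over the list alone, camera adjusted p = 7.46e-22, adjusted p = 0.0213 with an estimated correlation). Cell cycle genes gave 22 higher and 0 lower of 28 (median 1.89, 26 adjusted over the list alone, camera adjusted p = 1.48e-14, adjusted p = 0.373 with an estimated correlation). Ppara (-0.81 ± 0.17) and the lipid droplet gene Plin2 (-0.80 ± 0.20, adjusted p = 0.0256) fell. Plin2 did not pass when single animals were left out (adjusted p = 0.0505 without control 8A, 0.0528 without treated 18B, 0.0536 without treated 18D and 0.0591 without treated 80B). The total was 975 of 13963 genes, 673 higher and 302 lower.

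After 18 hours in formalin Cyp2b10 rose by 13.47 ± 0.33, Cyp2a5 by 3.54 ± 0.32 and the cell surface gene Prom1 by 2.01 ± 0.46 (adjusted p = 0.0211). Cyp2c66 was at least 390-fold and Cyp2c65 at least 52.3-fold higher against the floor. Conjugation enzymes gave 24 higher and 0 lower of 48 (median 0.63, 30 adjusted over the list alone, camera adjusted p = 3.36e-23, adjusted p = 0.0382 with an estimated correlation). CYP2B, CYP2C and CYP3A genes gave 11 higher and 0 lower of 18 (median 3.15, 12 adjusted over the list alone, camera adjusted p = 3.41e-22, adjusted p = 0.0288 with an estimated correlation). The call of Prom1 was lost with limma voom (adjusted p = 0.0676) and in single omissions (0.0501 without control 8C and 0.0555 without treated 80B). The total was 665 of 13623 genes, 470 higher and 195 lower, and 425 without treated 80B.

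After 3 months in formalin Cyp2b10 rose by 11.56 ± 0.44, Gsta2 by 3.42 ± 0.58 and the survivin gene Birc5 by 2.97 ± 0.53. The receptor gene Nr1i2, which encodes PXR, rose by 0.63 ± 0.13 (adjusted p = 0.0165, and 0.119 at equal thinned depth). Cyp2c66 was at least 356-fold higher. CYP2B, CYP2C and CYP3A genes gave 11 higher and 0 lower of 18 (median 3.16, 12 adjusted over the list alone, camera adjusted p = 2.28e-31, adjusted p = 0.00125 with an estimated correlation). Conjugation enzymes gave 18 higher and 0 lower of 44 (median 0.51, 23 adjusted over the list alone, camera adjusted p = 7.93e-18, adjusted p = 0.054 with an estimated correlation). For cell cycle genes the counts were 10 higher and 0 lower of 24 (median 1.47, 18 adjusted over the list alone, camera adjusted p = 8.88e-13, adjusted p = 0.252 with an estimated correlation). The total was 274 of 13018 genes, 216 higher and 58 lower. Simulated 2-fold changes were recovered at 62.7% here against 80.6% in frozen liver.

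With TAE heating Cyp2b10 rose by 12.86 ± 0.41, the carboxylesterase gene Ces2a by 3.57 ± 0.20 and the cyclin gene Ccnb2 by 3.23 ± 0.65. Ces1d, another carboxylesterase, rose by 1.81 ± 0.41 (adjusted p = 0.0234, 0.0583 without control 8D). Conjugation enzymes gave 19 higher and 0 lower of 45 (median 0.66, 27 adjusted over the list alone, camera adjusted p = 1.28e-24, adjusted p = 0.0362 with an estimated correlation). For cell cycle genes the counts were 17 higher and 0 lower of 26 (median 1.80, 23 adjusted over the list alone, camera adjusted p = 2.19e-18, adjusted p = 0.224 with an estimated correlation). The total was 455 of 13822 genes, 325 higher and 130 lower.

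In heat-only portions Cyp2b10 rose by 13.48 ± 0.46, Cyp2c65 by 6.16 ± 0.52 and the mitotic kinesin gene Kif20a by 2.57 ± 0.43. Cpt1a, the carnitine palmitoyltransferase of fatty acid oxidation, fell (log2 fold change -0.75 ± 0.14). All 7 testable mitochondrially encoded protein genes rose (median 0.91, 7 adjusted over the list alone, camera adjusted p = 5.77e-08, adjusted p = 0.187 with an estimated correlation). Their values included mt-Nd1 at 1.02 ± 0.21 and mt-Nd4 at 0.91 ± 0.22 (adjusted p = 0.0262, 0.0581 without control 82B, 0.0675 without control 8A, 0.0626 without control 8C and 0.0549 without control 8D). The share of counts on mitochondrial genes was 10.8% ± 3.52 with phenobarbital against 5.82% ± 0.897 (SD, n = 6 each, exact permutation p = 0.00433, adjusted p = 0.0346 over 8 states). In the other 7 states the adjusted p was 0.571 or more. The total was 688 of 13683 genes, 483 higher and 205 lower, with 425 without treated 20B, 440 without control 82B and 417 without control 8A.

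With the catalyst and AllPrep isolation Cyp2b10 rose by 12.43 ± 0.29, Gadd45b by 2.67 ± 0.42 and the NRF2 target Srxn1 by 1.01 ± 0.20. Fgf21 (-2.03 ± 0.52, adjusted p = 0.0365) and Angptl4, an inhibitor of lipoprotein lipase (-1.36 ± 0.32, adjusted p = 0.0206), fell. The call of Angptl4 was lost in 1 omission (adjusted p = 0.0513 without treated 18D) and that of Fgf21 in 8 (adjusted p = 0.0694 without control 8C, 0.0671 without control 8D, 0.0777 without control 21C, 0.0552 without treated 18B, 0.0798 without treated 18D, 0.0868 without treated 20B, 0.0755 without treated 75C and 0.0605 without treated 80B). CYP2B, CYP2C and CYP3A genes gave 12 higher and 0 lower of 19 (median 3.58, 13 adjusted over the list alone, camera adjusted p = 2.02e-23, adjusted p = 0.0114 with an estimated correlation). Cell cycle genes gave 20 higher and 0 lower of 27 (median 1.86, 26 adjusted over the list alone, camera adjusted p = 1.04e-17, adjusted p = 0.214 with an estimated correlation). The total was 688 of 13934 genes, 435 higher and 253 lower. It was 652 higher and 137 lower with scaling by library totals, which shifted the median of all genes by 0.07 log2.

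With the catalyst and PureLink isolation Cyp2b10 rose by 11.81 ± 0.27, Gsta1 by 5.52 ± 0.87, Akr1b7 by 6.47 ± 0.91 and Ccnb1 by 3.78 ± 0.73. Conjugation enzymes gave 25 higher and 0 lower of 48 (median 0.56, 28 adjusted over the list alone, camera adjusted p = 2.07e-19, adjusted p = 0.0615 with an estimated correlation). PPARα targets gave 1 higher and 5 lower of 25 (median -0.26, 11 adjusted over the list alone, camera adjusted p = 7.08e-05, adjusted p = 0.695 with an estimated correlation). The total was 665 of 14311 genes, 459 higher and 206 lower, or 584 and 125 with scaling by library totals, a median shift of 0.05 log2.

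**Figure D3:**
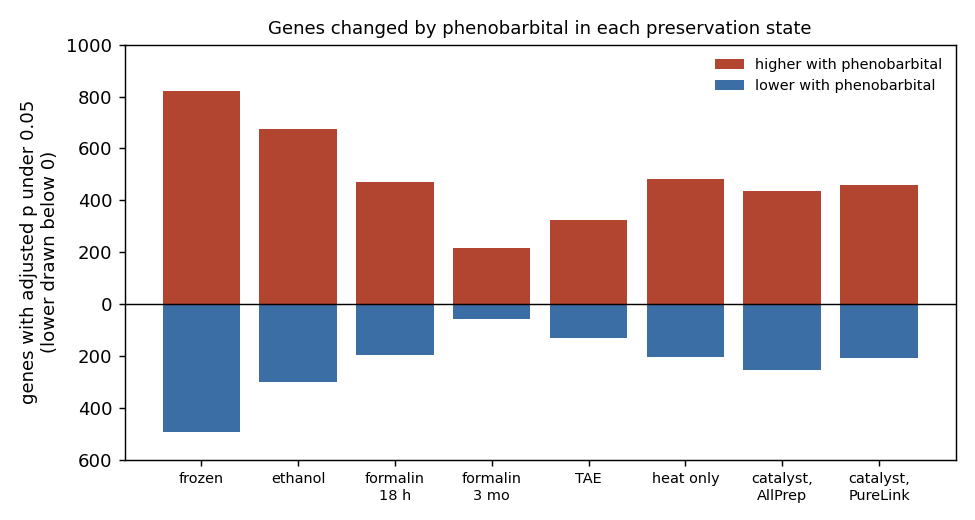
Number of genes with an adjusted p under 0.05 for phenobarbital against control (vertical axis, lower genes below 0) in each preservation state (horizontal axis), 6 against 6 animals each. Frozen liver gives 1313 genes and 3-month formalin 274.

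Genes that changed in frozen liver were then looked up in each preserved state. They included the genes listed above as rising in all 8 states. Of the frozen-changed genes tested in both, 710 of 1293 also changed in the same direction in ethanol-fixed liver (54.9%, exact 95% interval 52.1 to 57.6%). Independent lists of those sizes would share 49.5. The counts were 534 of 1280 in 18-hour formalin (41.7%, 34.4 if independent). After 3 months in formalin they were 244 of 1234 (19.8%, 17.6 to 22.1%, 14.8 if independent). For the treated portions they were 393 of 1277 with TAE (30.8%, 23.3 if independent) and 448 of 1268 with heat alone (35.3%, 35.1). With the catalyst they were 512 of 1287 after AllPrep (39.8%, 33.8) and 524 of 1294 after PureLink (40.5%, 33.6). In each of the 7 states 0 genes were called in opposite directions. Because the states share animals, the lookup was repeated with the frozen list from 6 animals and the preserved call from the other 6, over 20 draws. This gave 29.7% ± 15.5 (SD over draws) for 3-month formalin, 50.7% ± 21.8 for ethanol and 52% ± 21.6 for frozen liver against itself. Single draws ran from 7.08% to 62.6% for 3-month formalin and from 16% to 82% for ethanol.

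Whether the phenobarbital effect itself differed between a preserved state and frozen liver was tested as an interaction over 24 libraries per state. In heat-only portions, mitochondrially encoded protein genes had a larger phenobarbital effect than in frozen liver as a list, though 0 of 7 passed over all genes (median 0.86, 7 adjusted over the list alone, camera adjusted p = 1.64e-15, adjusted p = 0.0969 with an estimated correlation, 4 with the animal as a block). With the animal as a block 9 genes passed there, all with a larger effect in heat-only portions, and they were named after their values were seen. Chance cannot be excluded for this count, since 2 of 25 splits of the animals gave as many genes. The mitochondrial ones were the tRNA gene mt-Tm (1.07 ± 0.14, adjusted p = 0.00256), mt-Nd6 (1.10), mt-Nd5 (0.92), mt-Nd2 (0.89) and mt-Nd4 (0.82). The others were Fam171a1 (0.74), the matrix proteoglycan gene Prelp (0.46), the interferon regulator Irf7 (0.46) and the pericyte gene Rgs5 (0.61). Without the heat-only library of 18B the block gave 8 genes, and without the block 1 gene passed, Rcan3 (1.28 ± 0.20, adjusted p = 0.0307). In 3-month formalin, 0 of 20 endothelial genes passed (median 0.31, 2 adjusted over the list alone, camera adjusted p = 1.41e-11, adjusted p = 0.338 with an estimated correlation). With all libraries and no block, edgeR gave 0 genes in each of the 7 states, as did DESeq2 and limma voom. Over the 7 states 1.2% (ethanol) to 4.5% (heat only) of genes had an unadjusted p under 0.05, fewer than chance gives. The edgeR counts of 0 are thus weak evidence of no difference. The 3-month test recovered 11.9% of simulated 1.5-fold differences and 44.8% of 2-fold ones. With the animal as a block it recovered 43.3% and 68.7%, so differences of 1.5-fold were missed more often than found with either.

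The 14 remaining comparisons asked how each way of keeping or treating the tissue changed gene levels, with 12 libraries from the same 12 animals on each side. Against frozen liver, ethanol-fixed liver had lower levels of endothelial, Kupffer and stellate cell transcripts. F8, the coagulation factor VIII gene of sinusoidal endothelium, fell (log2 fold change -0.70 ± 0.10, adjusted p = 1.39e-05). So did the mannose receptor gene Mrc1 (-0.65 ± 0.09), the stromal proteoglycan gene Dcn (-0.63 ± 0.09) and the class I light chain gene B2m (-0.47 ± 0.05). Endothelial genes gave 18 lower and 1 higher of 20 (median -0.47, 18 adjusted over the list alone, camera adjusted p = 1.6e-07, adjusted p = 0.484 with an estimated correlation). Kupffer cell genes gave 14 lower and 0 higher of 20 (median -0.43, 14 adjusted over the list alone, camera adjusted p = 5.48e-05, adjusted p = 0.484 with an estimated correlation). For stellate cell genes the counts were 13 lower and 0 higher of 20 (median -0.40, 13 adjusted over the list alone, camera adjusted p = 0.00011, adjusted p = 0.484 with an estimated correlation). Fold changes also went with GC content here, and without that trend, removed after the result was seen, the medians of these 3 lists with the animal as a block were -0.50, -0.51 and -0.36, against -0.49, -0.45 and -0.35 with it. Nuclear-encoded respiratory chain genes fell in 48 of 66 cases (median -0.23, 51 adjusted over the list alone, camera adjusted p = 4.08e-14, adjusted p = 0.484 with an estimated correlation). Fam193b (1.25 ± 0.09), the adrenergic receptor gene Adrb3 (1.16 ± 0.11) and the imprinted RNA Meg3 (1.02 ± 0.25) rose. Long noncoding RNAs gave 14 higher and 1 lower of 26 (median 0.36, 15 adjusted over the list alone, camera adjusted p = 7.51e-05, adjusted p = 0.173 with an estimated correlation). In total 4561 of 13908 genes changed, 2367 higher and 2194 lower, or 7370 (3595 higher and 3775 lower) with the animal as a block and 3644 higher and 890 lower with scaling by library totals, which moved the median of all genes by 0.09 log2.

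After 18 hours in formalin, secreted hepatocyte products were lower than in frozen liver. Apoa1, the main HDL apolipoprotein, fell (log2 fold change -0.86 ± 0.06, adjusted p = 9.06e-11), and so did Apoe (-0.89 ± 0.08), the adhesive plasma protein gene Vtn (-0.85 ± 0.10) and the chaperone gene Calr (-1.01 ± 0.07). Of 30 secreted protein genes 22 fell and 2 rose (median -0.47, 24 adjusted over the list alone, camera adjusted p = 2.01e-10, adjusted p = 0.0219 with an estimated correlation and 0.154 with the animal as a block). Of 14 bile acid synthesis genes 10 fell and 0 rose (median -0.46, 10 adjusted over the list alone, camera adjusted p = 3.3e-06, adjusted p = 0.0192 with an estimated correlation and 0.118 with the animal as a block). Carboxylesterases and related enzymes fell in 17 of 27 cases (median -0.46, 19 adjusted over the list alone, camera adjusted p = 1.73e-06, adjusted p = 0.29 with an estimated correlation). Rprl3 (1.60 ± 0.11) and Rpph1 (1.14 ± 0.11), both RNase P RNA genes whose near-identical sequences could share reads, rose together with the cytochrome oxidase assembly gene Sco2 (0.94 ± 0.08). Small structured RNAs gave 15 higher and 1 lower of 19 (median 0.73, 15 adjusted over the list alone, camera adjusted p = 6.79e-06, adjusted p = 0.413 with an estimated correlation). Cytosolic ribosomal protein genes gave 60 higher and 0 lower of 77 (median 0.29, 62 adjusted over the list alone, camera adjusted p = 8.11e-15, adjusted p = 0.511 with an estimated correlation), such as Rpl39 (0.78 ± 0.10). In total 5704 of 13882 genes changed, 2844 higher and 2860 lower, or 5921 higher and 943 lower with scaling by library totals, which moved the median of all genes by 0.18 log2.

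After 3 months in formalin, small RNAs and mitochondrially encoded genes were higher than in frozen liver. The Y RNA gene Rny1 rose from 9.18 to 164 CPM (log2 fold change 4.16 ± 0.33, adjusted p = 2.18e-11), with Rny3 (4.14 ± 0.32), the minor spliceosome RNA Rnu11 (3.70 ± 0.21) and the vault RNA Vaultrc5 (3.69 ± 0.27). Small structured RNAs gave 17 higher and 0 lower of 19 (median 1.89, 17 adjusted over the list alone, camera adjusted p = 2.16e-06, adjusted p = 0.622 with an estimated correlation). Mitochondrially encoded proteins rose in 7 of 7 cases (median 2.24, 7 adjusted over the list alone, camera adjusted p = 2.56e-06, adjusted p = 0.352 with an estimated correlation), with mt-Nd2 at 2.73 ± 0.15. Small RNAs inside host genes can also collect host reads. The linker histone gene Hist1h1d (-2.38 ± 0.20), the keratin gene Krt8 (-1.92 ± 0.10) and Hsd3b7, an enzyme of bile acid synthesis (-1.83 ± 0.13), fell. Lower members were 52 of 66 nuclear-encoded respiratory chain genes (median -0.46, 54 adjusted over the list alone, camera adjusted p = 1.7e-08, adjusted p = 0.631 with an estimated correlation). Secreted protein genes fell in 23 of 30 cases (median -0.73, 23 adjusted over the list alone, camera adjusted p = 1.3e-06, adjusted p = 0.352 with an estimated correlation). For carboxylesterases and related enzymes the count was 22 of 27 (median -0.72, 22 adjusted over the list alone, camera adjusted p = 1.1e-05, adjusted p = 0.514 with an estimated correlation). Histone genes fell in 16 of 26 cases (median -1.02, 17 adjusted over the list alone, camera adjusted p = 0.00217, adjusted p = 0.631 with an estimated correlation). In total 8158 of 13477 genes changed, 4288 higher and 3870 lower.

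Longer fixation was compared directly, 3 months against 18 hours in formalin. mt-Nd2, a complex I subunit, rose from 1615 to 12140 CPM (log2 fold change 2.92 ± 0.17, adjusted p = 2.18e-12), with Vaultrc5 (3.20 ± 0.28) and Rny3 (3.03 ± 0.38). All 7 mitochondrially encoded protein genes rose (median 2.45, 7 adjusted over the list alone, camera adjusted p = 1.93e-10, adjusted p = 0.34 with an estimated correlation). Nuclear-encoded respiratory chain genes went the other way in 55 of 66 cases (median -0.47, 56 adjusted over the list alone, camera adjusted p = 2.77e-14, adjusted p = 0.953 with an estimated correlation), such as the complex I gene Ndufs5 (-1.38 ± 0.19). The myosin light chain gene Myl6 (-1.37 ± 0.10), the glutathione transferase gene Gstp1 (-1.21 ± 0.12) and Rprl3 (-1.74 ± 0.17) fell. In total 5987 of 13214 genes changed, 2942 higher and 3045 lower, or 1796 higher and 4372 lower with scaling by library totals, which moved the median of all genes by -0.12 log2.

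RNA heated in TAE after 3 months of formalin differed from frozen liver in plasma protein genes. Apoe fell from 10130 to 3043 CPM (log2 fold change -1.71 ± 0.10, adjusted p = 3.9e-13), with Ambp (-1.60 ± 0.15), Vtn (-1.55 ± 0.10) and the kininogen gene Kng1 (-1.55 ± 0.09). Of 30 secreted protein genes 28 fell and 0 rose (median -0.98, 28 adjusted over the list alone, camera adjusted p = 2.27e-13, adjusted p = 0.0285 with an estimated correlation and 0.0729 with the animal as a block). Of 27 carboxylesterases and related enzymes 24 fell (median -0.82, 24 adjusted over the list alone, camera adjusted p = 1.65e-08, adjusted p = 0.158 with an estimated correlation and 0.0407 with the animal as a block). Bile acid synthesis genes fell in 11 of 14 cases (median -0.88, 11 adjusted over the list alone, camera adjusted p = 3.5e-06, adjusted p = 0.0285 with an estimated correlation and 0.0658 with the animal as a block). Vaultrc5 (2.90 ± 0.24) and the dynein light chain gene Dynll2 (1.75 ± 0.06) rose. All 7 mitochondrially encoded protein genes were higher (median 1.25, 7 adjusted over the list alone, camera adjusted p = 8.22e-05, adjusted p = 0.405 with an estimated correlation). In total 8166 of 13833 genes changed, 4372 higher and 3794 lower, or 7123 higher and 2004 lower with scaling by library totals, which moved the median of all genes by 0.23 log2.

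Against unheated 3-month formalin portions, TAE heating gave lower small RNAs. Snora41, a small nucleolar RNA, fell from 12.6 to 1.46 CPM (log2 fold change -3.02 ± 0.34, adjusted p = 2.18e-06). Rnu11 (-1.86 ± 0.19) and the mitochondrial tRNA gene mt-Tt (-2.03 ± 0.20) also fell. Small structured RNAs gave 13 lower and 1 higher of 19 (15 adjusted over the list alone, camera adjusted p = 5.3e-08, adjusted p = 0.706 with an estimated correlation). Mitochondrially encoded protein genes fell in 6 of 7 cases (median -0.90, 6 adjusted over the list alone, camera adjusted p = 6.13e-07, adjusted p = 0.637 with an estimated correlation). Endothelial genes fell in 14 of 20 (median -0.43, 15 adjusted over the list alone, camera adjusted p = 3.1e-10, adjusted p = 0.637 with an estimated correlation). The prefoldin gene Pfdn6 (1.00 ± 0.15) and Myl6 (0.75 ± 0.10) rose. In total 2301 of 13296 genes changed, 1049 higher and 1252 lower, or 4583 (2260 higher and 2323 lower) with the animal as a block and 4064 higher and 368 lower with scaling by library totals, which moved the median of all genes by 0.18 log2.

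Heat-only portions had higher mitochondrial transcripts than frozen liver and lower nuclear respiratory genes. mt-Nd5, a complex I subunit, rose from 2435 to 9093 CPM (log2 fold change 1.81 ± 0.17, adjusted p = 1.54e-09). The mitochondrial leucyl-tRNA synthetase gene Lars2 rose by 1.84 ± 0.19. All 7 mitochondrially encoded protein genes rose (median 1.47, 7 adjusted over the list alone, camera adjusted p = 2.33e-06, adjusted p = 0.227 with an estimated correlation), while 63 of 66 nuclear-encoded respiratory chain genes fell (median -0.71, 63 adjusted over the list alone, camera adjusted p = 3.91e-25, adjusted p = 0.201 with an estimated correlation). Secreted protein genes fell in 28 of 30 cases (median -0.87, 29 adjusted over the list alone, camera adjusted p = 1.19e-12, adjusted p = 0.173 with an estimated correlation). Kupffer cell genes fell in 18 of 20 (median -0.84, 20 adjusted over the list alone, camera adjusted p = 2.51e-05, adjusted p = 0.397 with an estimated correlation). Gstp1 (-1.37 ± 0.07), the Kupffer cell lectin gene Fcna (-1.35 ± 0.13) and Snord17 (-2.26 ± 0.13) were lower. Mir6236, annotated as a microRNA, was higher (2.95 ± 0.26), and its counts may include reads of overlapping transcripts. In total 7912 of 13889 genes changed, 3940 higher and 3972 lower, or 7358 higher and 1913 lower with scaling by library totals, which moved the median of all genes by 0.26 log2.

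Heat-only portions had lower small RNAs and ribosomal protein genes than 3-month formalin portions, whose isolation kit is not given, so heat and kit are not separated here. Rny1 fell from 164 to 7.33 CPM (log2 fold change -4.45 ± 0.32, adjusted p = 1.37e-10) and Rny3 by the log2 fold change -4.27 ± 0.32. Small structured RNAs were lower in 17 of 19 cases (median -2.02, 17 adjusted over the list alone, camera adjusted p = 1.16e-12, adjusted p = 0.796 with an estimated correlation). Cytosolic ribosomal protein genes were lower in 54 of 77 (median -0.46, 55 adjusted over the list alone, camera adjusted p = 1.16e-12, adjusted p = 0.964 with an estimated correlation). Endothelial genes were lower in 16 of 20 (median -0.62, 16 adjusted over the list alone, camera adjusted p = 1.28e-08, adjusted p = 0.796 with an estimated correlation). Hsd3b7 (2.00 ± 0.17), the thymidine phosphorylase gene Tymp (1.72 ± 0.21) and the splicing factor gene Srsf5 (1.51 ± 0.13) rose. In total 6222 of 13283 genes changed, 3121 higher and 3101 lower, or 5101 higher and 1596 lower with scaling by library totals, which moved the median of all genes by 0.17 log2.

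Catalyst-treated AllPrep portions had lower plasma protein and respiratory genes than frozen liver. Apoe fell from 10130 to 4558 CPM (log2 fold change -1.14 ± 0.09, adjusted p = 1.08e-10), with Fcna (-1.12 ± 0.10) and the linker histone gene Hist1h1e (-1.10 ± 0.08). Secreted protein genes were lower in 28 of 30 cases (median -0.70, 28 adjusted over the list alone, camera adjusted p = 1.83e-16, adjusted p = 0.00423 with an estimated correlation and 0.062 with the animal as a block). Nuclear-encoded respiratory chain genes fell in 60 of 66 (median -0.51, 61 adjusted over the list alone, camera adjusted p = 9.39e-24, adjusted p = 0.186 with an estimated correlation). Histone genes fell in 20 of 26 (median -1.02, 21 adjusted over the list alone, camera adjusted p = 1.24e-06, adjusted p = 0.25 with an estimated correlation). Fam193b (1.45 ± 0.10) and Adrb3 (1.34 ± 0.11) rose. Long noncoding RNAs rose in 18 of 26 cases (median 0.45, 19 adjusted over the list alone, camera adjusted p = 3.43e-06, adjusted p = 0.0278 with an estimated correlation and 0.062 with the animal as a block). Mitochondrially encoded protein genes rose in 7 of 7 (median 0.78, 7 adjusted over the list alone, camera adjusted p = 3.11e-06, adjusted p = 0.186 with an estimated correlation). In total 7053 of 13997 genes changed, 3893 higher and 3160 lower, or 7171 higher and 1499 lower with scaling by library totals, which moved the median of all genes by 0.21 log2.

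Catalyst-treated PureLink portions had lower ribosomal protein and respiratory genes than frozen liver. Romo1, a small mitochondrial inner membrane protein gene, fell from 19.2 to 7.53 CPM (log2 fold change -1.35 ± 0.09, adjusted p = 4.15e-12). Apoe (-1.27 ± 0.08) and the ATP synthase gene Atp5k (-1.22 ± 0.05) fell too. Cytosolic ribosomal protein genes were lower in 74 of 77 cases (median -0.55, 74 adjusted over the list alone, camera adjusted p = 3.41e-23, adjusted p = 0.244 with an estimated correlation). Nuclear-encoded respiratory chain genes were lower in 64 of 66 (median -0.78, 64 adjusted over the list alone, camera adjusted p = 6.31e-31, adjusted p = 0.109 with an estimated correlation). Fold changes went with gene length here, and without that trend the blocked medians of these 2 lists of short genes were -0.23 and -0.34, against -0.56 and -0.79 with it. Erythroid genes fell in 7 of 9 (median -0.92, 8 adjusted over the list alone, camera adjusted p = 0.0021, adjusted p = 0.355 with an estimated correlation). Long noncoding RNAs rose in 23 of 26 cases (median 0.60, 23 adjusted over the list alone, camera adjusted p = 1.1e-07, adjusted p = 0.0348 with an estimated correlation). mt-Nd6, a complex I subunit, rose by 1.56 ± 0.16. In total 8364 of 14132 genes changed, 4449 higher and 3915 lower, or 8180 higher and 1726 lower with scaling by library totals, which moved the median of all genes by 0.27 log2.

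Portions with catalyst and AllPrep had lower small and mitochondrial RNAs than 3-month formalin portions, again without a separation of treatment and kit. Rny1 (-4.67 ± 0.35, adjusted p = 1.18e-10), Rny3 (-4.63 ± 0.32) and Vaultrc5 (-3.89 ± 0.29) fell. Lower members were 18 of 19 small structured RNAs (median -2.10, 18 adjusted over the list alone, camera adjusted p = 2.51e-12, adjusted p = 0.69 with an estimated correlation). Mitochondrially encoded protein genes were lower in 7 of 7 (median -1.36, 7 adjusted over the list alone, camera adjusted p = 1.68e-06, adjusted p = 0.69 with an estimated correlation). Of 77 cytosolic ribosomal protein genes 50 fell (median -0.38, 53 adjusted over the list alone, camera adjusted p = 6.58e-10, adjusted p = 0.985 with an estimated correlation). Hsd3b7 rose from 2.87 to 10.7 CPM (log2 fold change 1.92 ± 0.15), Tymp by 1.68 ± 0.19 and Srsf5 by 1.52 ± 0.12. In total 6364 of 13433 genes changed, 3195 higher and 3169 lower, or 5097 higher and 1803 lower with scaling by library totals, which moved the median of all genes by 0.16 log2.

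The like comparison for portions with catalyst and PureLink gave Rny1 at 164 CPM in 3-month formalin and 4.71 CPM with catalyst (log2 fold change -5.08 ± 0.32, adjusted p = 2.26e-12). Small structured RNAs fell in 17 of 19 cases (median -2.03, 17 adjusted over the list alone, camera adjusted p = 2.6e-08, adjusted p = 0.989 with an estimated correlation). Mitochondrially encoded protein genes were lower in 6 of 7 (median -1.46, 6 adjusted over the list alone, camera adjusted p = 0.000285, adjusted p = 0.989 with an estimated correlation). Cytosolic ribosomal protein genes fell in 72 of 77 (median -0.69, 73 adjusted over the list alone, camera adjusted p = 4.39e-19, adjusted p = 0.989 with an estimated correlation). Adam4, a metalloprotease family gene (2.87 ± 0.24), Hsd3b7 (2.45 ± 0.16) and Srsf5 (1.96 ± 0.11) rose. In total 8107 of 13556 genes changed, 4173 higher and 3934 lower, or 6122 higher and 2356 lower with scaling by library totals, which moved the median of all genes by 0.20 log2.

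Catalyst-treated AllPrep portions were compared with heat alone with the same kit. Mitochondrially encoded protein genes fell in 5 of 7 cases (median -0.73, 7 adjusted over the list alone, camera adjusted p = 7.49e-14, adjusted p = 0.12 with an estimated correlation). These included mt-Nd5 at -0.87 ± 0.17 (adjusted p = 0.017) and mt-Nd2 at -0.85 ± 0.17. The share of counts on mitochondrial genes was higher in the heat-only phenobarbital group (10.8%) than in its controls (5.82%). In total 123 of 13807 genes changed, 86 higher and 37 lower, or 1930 (1116 higher and 814 lower) with the animal as a block and 42 higher and 47 lower with scaling by library totals, which moved the median of all genes by -0.02 log2. Without the heat-only library of the treated animal 18B, which had the highest mitochondrial share, the count was 59, and 1589 with the block.

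The isolation kits were compared after the same catalyst incubation. Cytosolic ribosomal protein genes were lower with PureLink in 21 of 77 cases (median -0.32, 73 adjusted over the list alone, camera adjusted p = 2.71e-32, adjusted p = 0.763 with an estimated correlation, 76 with the animal as a block). Rps29 was at -0.52 ± 0.12 (adjusted p = 0.0313) and Rpl32 at -0.47 ± 0.11. Nuclear-encoded respiratory chain genes fell in 29 of 66 (median -0.22, 58 adjusted over the list alone, camera adjusted p = 6.93e-31, adjusted p = 0.353 with an estimated correlation, 60 with the animal as a block), with Atp5k at -0.40 ± 0.08 and the complex III gene Uqcr10 at -0.38 ± 0.08. Without the trend on gene length the blocked medians were -0.23 and -0.13, against -0.31 and -0.22 with it. At equal thinned depth Rpl32 (adjusted p = 0.16), Atp5k (0.279) and Uqcr10 (0.18) did not pass. In total 328 of 14124 genes changed, 163 higher and 165 lower, or 5207 (2509 higher and 2698 lower) with the animal as a block.

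**Figure D4:**
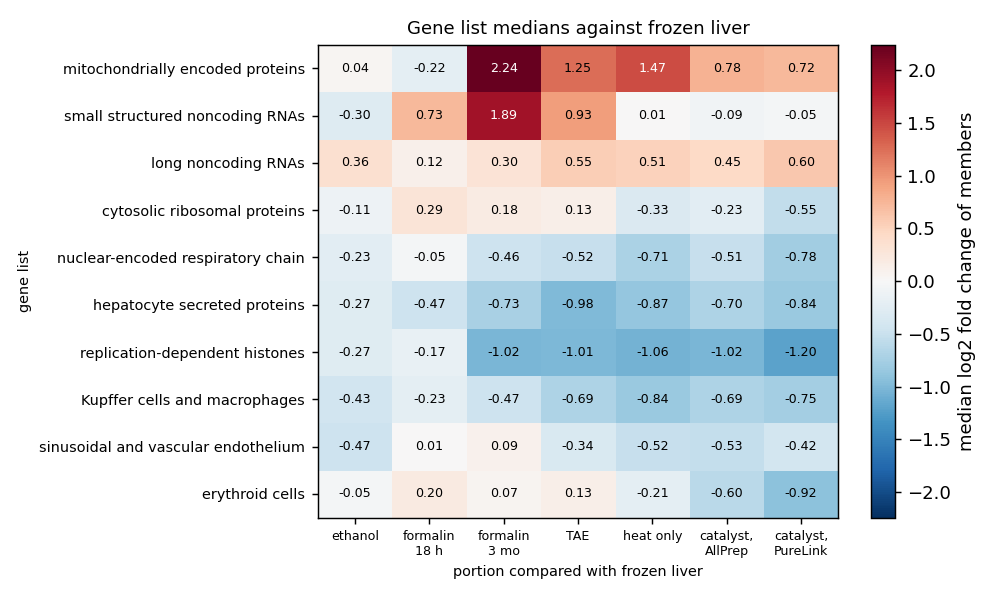
Median log2 fold change of the members of 10 gene lists (vertical axis) in each of the 7 preserved states (horizontal axis) against frozen liver, 12 animals on each side (blue for lower, red for higher, values printed in the cells). Mitochondrially encoded proteins are above 0 from 3-month formalin on (2.24, then 1.25 with TAE, 1.47 with heat alone, 0.78 with AllPrep and 0.72 with PureLink catalyst), and replication-dependent histones are below 0 in those 5 states, with the same signs under scaling by library totals.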

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

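The tests between separate groups of 6 frozen animals, the test of standard errors, the mean over 10 thinnings and all tests of the mitochondrial share in heat-only portions were chosen only after the result was seen.

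Fewer genes changed with phenobarbital in 3-month formalin (274) than in frozen liver (1313), a ratio of 4.79. Thinned to the shallowest library, the ratio was 2.3 (2.15 to 2.54 over 10 thinnings), above the bound of 1.5 set before, which argues against library size as the whole cause. Wider spread between libraries may contribute. Over the 12902 genes tested in both states, the standard error in 3-month formalin was 1.75 times that in frozen liver at the median (1.67 to 1.81 with 1 animal left out in turn). With all libraries thinned to the shallowest it was 1.215 (1.209 to 1.222 over 10 thinnings, 1.203 to 1.241 with 1 animal left out), little above the bound of 1.2. Smaller fold changes cannot be told apart from none, since the slope of 3-month formalin on frozen fold changes between different animals was 0.845 (0.613 to 1.04 over 20 draws), spanning the bound of 0.8, against 0.895 for frozen on frozen liver.

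Between 3-month formalin and frozen liver 8158 genes differed, which could be a trend with transcript length or GC content. With the animal as a block, 4615 called genes changed by at least 0.5 log2. After a smooth trend on gene length was removed, 88.7% of those with a length kept such a change (exact interval 87.7 to 89.6%). After one on GC content it was 81.5% (80.4 to 82.7%). Both values argue against those trends as the whole cause. No isolation or library batch is given by the labels, and none was tested. An effect of fixation itself stays open.

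In heat-only portions the mitochondrial share rose further above frozen with phenobarbital than in controls, by 4.67 percentage points (exact permutation p = 0.00433, 6 against 6 animals). Without 18B, the treated animal with the highest share, the heat-only means were 9.61% and 5.82% (exact permutation p = 0.004329), which argues against a single library as the cause. An effect of phenobarbital present in the liver itself is argued against by the other 7 portions of the same animals, where the ratio of treated to control means was at most 1.14 (ethanol, lowest 0.942) against 1.85 here. No batch of incubation or isolation in this state is given by the labels, and none was tested, so the cause stays open. With the animal as a block 9 genes, 5 of them mitochondrial, passed for a phenobarbital effect that differs between heat-only and frozen portions, and chance cannot be excluded for that count, reached in 2 of 25 splits.

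Single libraries that stood apart from the other 5 of their group came up in 8 of 120 sets of values, where chance gives about 1 in 20, or 6. Library totals stood apart for 8A in 3-month formalin controls (1264563 counts), 21C in PureLink catalyst controls (13911213 counts) and 8C in frozen controls (16456535 counts). In 3-month formalin the treated animal 80B had 14521 detected genes after thinning. The mitochondrial share of 21C in ethanol controls was 3.49%. Cyp2b10 was at 4.24 CPM in the shallow 3-month formalin control 8A. In frozen controls Por was at 111 CPM in 8A and Gstm3 at 19.5 CPM in 8C. Spike-in sequences, which the labels do not mention, had 96 counts in the TAE library and 6 in the AllPrep catalyst library of control 82B.

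The drawn splits argued against chance for the phenobarbital response in all 8 states. In each, 1 of 60 splits of the 12 animals, the real one, gave as many genes. The real count and the highest of the other splits were 1313 against 2 (frozen liver), 975 against 1 (ethanol), 665 against 6 (18-hour formalin) and 274 against 37 (3-month formalin). In the treated portions they were 455 against 24 (TAE), 688 against 9 (heat-only), 688 against 2 (AllPrep catalyst) and 665 against 46 (PureLink catalyst). For the 14 comparisons between states 1 of 21 splits, the real one, gave as many genes with or without the block. That is the smallest share that 21 splits can give, not adjusted over the comparisons, so it alone cannot exclude chance. These splits swapped state labels within some animals, parting as many pairs as the real one. In each comparison the others had a median of 0 genes. Real and highest other counts against frozen liver were 4561 against 0 (ethanol), 5704 against 0 (18-hour formalin), 8158 against 5362 (3-month formalin) and 8166 against 4853 (TAE). For the portions incubated at 55 °C they were 7912 against 3116 (heat-only), 7053 against 0 (AllPrep catalyst) and 8364 against 0 (PureLink catalyst). Against 3-month formalin they were 2301 against 0 (TAE), 6222 against 0 (heat-only), 6364 against 1658 (AllPrep catalyst) and 8107 against 0 (PureLink catalyst). The other comparisons gave 5987 against 2175 (3-month formalin over 18-hour formalin), 123 against 0 (AllPrep catalyst over heat-only) and 328 against 0 (PureLink catalyst over AllPrep catalyst). With the animal as a block, all in the same order, the counts against frozen liver were 7370 against 0, 8036 against 0, 8893 against 0 and 9537 against 0. For the incubated portions they became 9274 against 4158, 8849 against 0 and 10068 against 7695. Against 3-month formalin the blocked counts were 4583 against 0, 7420 against 0, 7766 against 1690 and 9047 against 0. The other blocked comparisons gave 7119 against 3092, 1930 against 6 and 5207 against 0.

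For the interactions without the block the real count was 0 and the highest other 0 in each of the 7 states. Any split gives at least 0 genes, as 25 of 25 did, so those splits cannot say whether chance gives a count of 0, and the same holds for the 6 blocked counts of 0. For the heat-only count of 9 with the block chance cannot be excluded, since 2 of 25 splits gave as many. The blocked real and highest other counts were 0 against 4 (ethanol), 0 against 2 (18-hour formalin), 0 against 3 (3-month formalin) and 0 against 419 (TAE). For the incubated portions they were 9 against 43 (heat-only), 0 against 207 (AllPrep catalyst) and 0 against 0 (PureLink catalyst). The highest splits, with 43 genes against 9, 207 against 0 and 419 against 0, point to a structure of the samples other than treatment, and what it is was not tested.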

How the results depend on the processing

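Leaving out the shallowest library, the library richest in small RNAs or the heat-only library of 18B, thinning to the second lowest total, removing trends on length or GC content and limma on the deposited log2 values were chosen only after the result was seen.

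Depth limited the counts. At the depth of the shallowest library, phenobarbital changed 343, 296, 269, 153, 208, 266, 253 and 268 genes in frozen, ethanol, 18-hour formalin, 3-month formalin, TAE, heat-only, AllPrep catalyst and PureLink catalyst portions. The 7 preserved states in that order against frozen liver gave 1556, 2499, 5062, 4560, 4399, 3501 and 4220 genes. TAE, heat-only, AllPrep and PureLink portions against 3-month formalin gave 1058, 3687, 3810 and 4898. The other state comparisons gave 3600 (3-month formalin over 18-hour formalin), 15 (AllPrep catalyst over heat-only) and 26 (PureLink catalyst over AllPrep catalyst). These counts were lower because fewer reads remained. Recovery of frozen phenobarbital genes at that depth was 64.6%, 58.4%, 38.3%, 47.9%, 50%, 51.6% and 57.5% in the 7 preserved states in the same order. Among genes changed at least 2-fold in frozen liver it was 90.7%, 81.1%, 65.9%, 77.3%, 85.1%, 86.4% and 87.9%. With separate groups of 6 animals and shorter frozen lists, mean recovery was 50.7% (ethanol), 41.8% (18-hour formalin), 29.7% (3-month formalin) and 37.8% (TAE). In the incubated portions it was 40.8% (heat-only), 41.9% (AllPrep catalyst) and 44.4% (PureLink catalyst). Thinned to the second lowest total, frozen phenobarbital genes numbered 867 and those of PureLink over AllPrep 209. The other 20 counts above 0 stayed within 1.5 times.

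With 1 animal left out in turn the phenobarbital counts ranged over 872 to 1487 (frozen), 650 to 1098 (ethanol), 425 to 796 (18-hour formalin) and 191 to 275 (3-month formalin). In the treated portions they ranged over 334 to 493 (TAE), 417 to 776 (heat-only), 505 to 771 (AllPrep catalyst) and 456 to 709 (PureLink catalyst). Of 96 omissions 5 moved a count by over 1.5 times. They were treated 80B in frozen (872) and 18-hour formalin (425) portions and treated 20B (425), control 82B (440) and control 8A (417) in heat-only portions. DESeq2 called 1015 (18-hour formalin), 484 (3-month formalin), 750 (TAE), 1036 (heat-only) and 1085 (AllPrep catalyst) genes for phenobarbital. It called 370 for AllPrep catalyst over heat alone and 961 for PureLink over AllPrep. In the comparison of kits limma voom called 585, scaling by library totals 196 and no filter 88. Library totals gave 4432 for TAE over 3-month formalin, and no filter 39 for AllPrep catalyst over heat alone. The cause was not tested for any of these.

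The animal as a block raised the counts to 7370 (ethanol over frozen), 4583 (TAE over 3-month formalin), 1930 (AllPrep catalyst over heat-only), 5207 (PureLink over AllPrep catalyst) and 9 (the heat-only interaction). Gene lists passing camera numbered 25 with the block against 13 without for ethanol over frozen and 14 against 9 for 3-month over 18-hour formalin. They were 8 against 5 for heat-only over 3-month formalin and 18 against 10 for PureLink over AllPrep. For the interactions they numbered 14 against 4 (ethanol), 13 against 2 (18-hour formalin), 20 against 8 (3-month formalin) and 10 against 5 (TAE). In the incubated portions these were 20 against 13 (heat-only), 24 against 11 (AllPrep catalyst) and 23 against 9 (PureLink catalyst). The cause was not tested. Without the heat-only library of 18B, AllPrep catalyst over heat-only gave 59 genes, or 1589 with the block. The heat-only interaction gave 1, or 8 with the block, on 1 library fewer.

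With an estimated in place of a preset correlation, which allows for members that vary together, lists passing for phenobarbital fell from 14 to 1 (frozen liver), 16 to 1 (ethanol), 14 to 2 (18-hour formalin) and 16 to 1 (3-month formalin). In the treated portions they fell from 12 to 2 (TAE), 20 to 1 (heat-only), 16 to 1 (AllPrep catalyst) and 17 to 1 (PureLink catalyst). Against frozen liver they fell from 13 to 0 (ethanol), 14 to 2 (18-hour formalin), 15 to 0 (3-month formalin), 20 to 2 (TAE), 23 to 0 (heat-only), 24 to 5 (AllPrep catalyst) and 26 to 4 (PureLink catalyst), and against 3-month formalin from 9 to 0 (TAE), 5 to 0 (heat-only), 5 to 0 (AllPrep catalyst) and 7 to 0 (PureLink catalyst). The other comparisons fell from 9 to 0 (3-month formalin over 18-hour formalin), 16 to 0 (AllPrep catalyst over heat-only) and 10 to 0 (PureLink catalyst over AllPrep catalyst), and each interaction to 0. With the block as well, lists passing at an estimated correlation numbered 0 (18-hour formalin), 3 (TAE), 0 (AllPrep catalyst) and 1 (PureLink catalyst) against frozen liver, and 0 in the other 10 state comparisons and 7 interactions. Without mitochondrially encoded genes the share of the 10 most abundant genes against frozen turned from 2.18 to -2.06 percentage points in 3-month formalin. In heat-only portions it turned from 0.0311 to -3.75, because those genes take up much of that share. Detected genes after 3 months in formalin turned from -150 to 31.1 against frozen, and neither difference passed. RLE scaling, 1 gene set for all comparisons, limma on the deposited log2 values and leaving out the shallowest library or the one richest in small RNAs moved 0 of the counts by over 1.5 times. Without a trend on length the blocked median of ribosomal protein genes in AllPrep catalyst over frozen portions turned from -0.246 to 0.0329, or 0.0307 without one on GC content too. Of 2643 values of 166 pairs of a named gene and a comparison under the alternatives, 2588 kept their direction and side of the threshold, 51 no longer passed, 4 newly passed and 0 turned.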

Other observations

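Beyond drug metabolism, phenobarbital changed single members of other lists in frozen liver, 6 against 6 animals. The transporter genes Slco1a4 (1.58 ± 0.23) and Abcc2, a canalicular exporter (0.69 ± 0.09), rose. Of 20 hepatic transporters 5 rose and 1 fell (median 0.04, 7 adjusted over the list alone, camera adjusted p = 0.113, adjusted p = 0.813 with an estimated correlation). The collagen gene Col3a1 (0.71 ± 0.20) and the matricellular gene Sparc (0.42 ± 0.10) rose, with 4 of 20 stellate cell genes (median 0.13, 9 adjusted over the list alone, camera adjusted p = 0.0537, adjusted p = 0.724 with an estimated correlation). So did the histone genes Hist1h3b (2.13 ± 0.47) and Hist1h1a (1.69 ± 0.36), with 4 of 29 (median 0.39, 4 adjusted over the list alone, camera adjusted p = 0.000474, adjusted p = 0.679 with an estimated correlation). The call of Col3a1 (adjusted p = 0.0403) was lost with limma voom (0.0529), with limma on the deposited values (0.0522) and in single omissions (0.0676 without control 8C, 0.0763 without control 21C, 0.085 without control 82B, 0.0817 without control 90C, 0.0825 without treated 18D, 0.0891 without treated 20B and 0.0888 without treated 80B). That of Sparc was lost at equal thinned depth (0.096). The urea cycle gene Arg1 fell (log2 fold change -0.31 ± 0.08), with 3 of 19 periportal genes (median -0.13, 3 adjusted over the list alone, camera adjusted p = 0.00771, adjusted p = 0.354 with an estimated correlation). The call of Arg1 (adjusted p = 0.0343) was lost with no filter (0.0753), at both thinned depths (0.104 and 0.0519) and in single omissions (0.0669 without control 8A, 0.068 without control 8C, 0.0742 without control 8D, 0.0535 without control 82B, 0.072 without control 90C, 0.0791 without treated 18D, 0.0619 without treated 20D and 0.0651 without treated 75C). Kupffer cell genes gave 0 higher of 20 (median 0.26, 0 adjusted over the list alone, camera adjusted p = 0.0256, adjusted p = 0.85 with an estimated correlation).

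Against frozen liver, 3-month formalin portions also had lower levels of members of 4 further lists, 12 libraries on each side. The urea cycle gene Asl (-1.64 ± 0.12) fell with 14 of 19 periportal genes (median -0.50, 14 adjusted over the list alone, camera adjusted p = 4.88e-05, adjusted p = 0.352 with an estimated correlation). The alanine transaminase gene Gpt (-1.45 ± 0.10) fell with 12 of 15 genes of gluconeogenesis and amino acid catabolism (median -0.55, 12 adjusted over the list alone, camera adjusted p = 0.000242, adjusted p = 0.352 with an estimated correlation). The haptoglobin gene Hp (-1.66 ± 0.33) fell with 10 of 22 acute phase genes (median -0.95, 10 adjusted over the list alone, camera adjusted p = 0.0397, adjusted p = 0.918 with an estimated correlation, 17 with the animal as a block). The chaperone gene Hspa5 (-1.38 ± 0.13) fell with 9 of 17 genes of the unfolded protein response (median -0.45, 9 adjusted over the list alone, camera adjusted p = 0.0304, adjusted p = 0.631 with an estimated correlation). Of 19 major urinary protein genes 7 rose and 7 fell, Mup5 by 2.10 ± 0.16 and Mup7 by -1.91 ± 0.15, and their near-identical copies could share reads.

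Trends of fold changes with gene length and GC content were computed only after the result was seen, across protein-coding genes, which are not independent replicates. Length accounted for 26.4% of the variance of log2 fold changes between PureLink catalyst and frozen portions, 18.5% for AllPrep catalyst, 16.2% for heat-only and 3.71% for 3-month formalin portions against frozen, and 16.1% between the kits. In PureLink portions the shortest of 5 equal groups of genes had a median of -0.41 and the longest group 0.13. Without that trend the blocked median of respiratory chain genes against frozen went from -0.71 to -0.33 (heat-only) and from -0.52 to -0.21 (AllPrep catalyst). GC content accounted for 24.9% of the variance between ethanol and frozen portions and 21.3% between 3 months and 18 hours in formalin.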
